A study of Homo sapiens and Oncorhynchus mykiss with 252 samples.

How the data were processed

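The series held 252 libraries in 11 count tables from 3 established cell lines: Caco-2 (human, colorectal), Hep G2 (human, liver) and RTgill-W1 (rainbow trout, gill). Per the labels' protocols, 35000 cells were seeded per well, exposure began 24 h later, and libraries were made from cell lysate with a high-throughput 3' RNA-seq kit. The human lines received DMSO, H2O2 or methanol (MeOH), and the trout line received DMSO or a compound the labels call DCA. Each chemical was given at 8 concentrations with 3 wells each. The controls were 18 wells in each human line and 24 wells in the trout line. The labels do not give a unit for the concentrations, so they are printed here without one. Per the submitters' processing notes, STAR, DESeq2 and limma were used and the reference was GRCh38. The versions, the roles of these tools and the reference used for the trout reads were not given in the sources used here.

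The deposited values were whole-number read counts per gene, taken as raw counts, with 37728 genes in the human tables and 49260 gene ids in the trout tables. Of the 252 columns, 203 matched a library by its name and 49 by cell line, chemical and well. No 2 libraries were identical and 0 columns were left unused. The trout ids could not be named, since 0 of them had a symbol in the reference tables used here. Library totals ran from 48018 to 1132903 counts in Caco-2 (control median 622199), from 66446 to 893546 in Hep G2 (control median 443811) and from 20270 to 2431548 in RTgill-W1 (control median 1090943). Libraries under 10% of the control median of their line were left out of the fits. This removed 1 well of the highest H2O2 concentration in Caco-2 and 1 well of the DCA concentration 7.5 in RTgill-W1.

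Concentrations were read from the library names. In RTgill-W1 the treatment field of the labels gave another order, the same as an alphabetical sort of the library names. In Hep G2 that field gave 5.46 for DMSO and 1.88 for H2O2 at the top, where the library names gave 10 and 3.33. The column names of the deposited Hep G2 tables for DMSO and H2O2 carry lower doses than the library names too. These are equal or near to those of the treatment field, except at the highest H2O2 concentration, with 1 against 1.88. The column names also give the 2 highest H2O2 concentrations the same dose. The doses and tPODs of these tables therefore rest on the library names alone. Each concentration of a chemical filled 1 row of the plate, which it shared with the same concentration number of the other chemicals. The Caco-2 controls lay in rows C to H, so rows A and B, with the 2 highest concentrations, held no control. The Hep G2 controls lay in all rows but C and D, and the trout controls in every row. The replicate number of the treated wells marked a block of 4 adjacent plate columns. No label says that the wells of a group were separate cultures, so the p-values measure only the spread between wells, which may be technical.

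Each line and chemical was fitted once, with the controls and all 8 concentrations, by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. TMM normalisation and filterByExpr were used, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. An any-dose test took all 8 concentration terms together, and each concentration was then compared with the controls. A concentration was called active when it and every higher concentration had at least 20 genes called. Line differences were the interaction of line and treatment at the highest concentration, and solvent differences compared DMSO with MeOH within a line. Levels are CPM, which are counts scaled to the TMM-adjusted library total of the genes tested in that fit. The level of a gene in the same wells can therefore differ slightly between fits. Levels are given as mean ± SD, and log2 fold changes carry ± the standard error. Adjusted p-values of genes in all texts come from this edgeR test unless another tool is named.

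Fixed gene lists were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, and again with a correlation estimated from the data. Of 28 lists, 23 were tested in at least 1 human comparison and 21 to 23 in each, and the rest had too few measured genes or could not be used. A gene counts toward a list when it passed over all genes, and for lists that passed the count adjusted over the list alone is given beside it. The lists, comparisons, thresholds and alternatives were fixed before the data were examined, except where a text says otherwise.

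A transcriptomic point of departure (tPOD) was computed in each line and chemical from the genes that passed the any-dose test and changed at least 1.5-fold. A constant and linear, power, exponential and Hill curves were compared by AICc on log2 CPM with a prior count of 2. The gene's benchmark dose was the dose at which the curve had moved by 1 SD of the controls. A dose was kept when the lack-of-fit p was over 0.1 and the dose lay between 10 times below the lowest and the highest concentration. The tPOD was the 10th percentile of at least 10 gene doses, with a 95% interval from 50 resamplings of the wells. The genes entered and the normalisation were kept fixed in these resamplings. The interval therefore leaves out the choice of genes and can be too narrow. For DCA, the tPODs without each replicate number lay below its lower end.

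Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, other depth limits, the replicate block, the plate row as a covariate, each replicate number left out in turn, only the highest concentration in the fit, and the treatment-field doses. For the tPOD they also included a prior count of 0.5, a response of 2 SD, the 25th lowest gene, no fold filter, and leaving out the highest concentration. An alternative with replicate blocks 1 and 2 only was added after the data were seen.

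In RTgill-W1 the replicate block also paired the wells of different groups. Control wells entered this check as the mean of each block. Of the pairs in the same block, 100 of 100 for DCA and 108 of 108 for DMSO had residuals correlated above 0.1. The lowest r was 0.179 and 0.213. Pairs with a control mean passed in 23 of 23 and 24 of 24 cases. Results with the block as a factor are therefore given beside the RTgill-W1 results.

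In the 3 wells of the highest H2O2 concentration in Hep G2, the counts followed a gene order that ignores hyphens, while the gene column did not. The 2 orders differ at 2997 of 37728 places. Genes at those places were left out of every fit that used these wells. This departure was decided after seeing the data, and results with the counts as deposited and with them re-sorted are given beside the result.

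Genes were named by a fixed rule. At the highest concentration these were up to 10 genes each way with the largest log2 fold change among those that passed, with at least 20 CPM in the higher group and every treated well on the same side of the control median, and the text may stop after 5. At the lowest active concentration, and for differences between lines or solvents, the first 5 each way were taken. Of each gene list up to 4 members with the smallest p-values were named, and members moving the other way. For genes named at a concentration by the size of their change, a group with 0 counts makes the fold a lower bound taken at 3 counts. Where a group had 1 to 3 counts, a ratio with an interval is given for them. These bounds and intervals cover counting error only. Other list members and the differences between lines or solvents carry fitted values, also where counts were few. For histone, long non-coding and antisense genes and close gene copies, how reads were assigned is not stated in the sources used here, so their values are less certain.

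The procedures were tested on simulated data. For the fits, 200 changed genes were drawn from those above 20 CPM in the controls. Wells were simulated without replicate blocks and without an offset between controls and treated wells. The percentages found and the false calls therefore hold only for such genes and wells. The percentage of 2-fold changes found at the highest concentration was 68.7, 46.3 and 88.1 in Caco-2 for DMSO, H2O2 and MeOH, 53.7, 62.7 and 83.6 in Hep G2, and 11.9 and 17.9 in RTgill-W1 for DCA and DMSO. For 4-fold changes it was 97, 83.3, 100, 86.4, 95.5, 100, 75.8 and 81.8, in the same order. False calls numbered from 0 to 9 among 6709 to 15215 genes, with 0 errors of sign. A simulated list of 30 moved genes gave p = 6.4e-13 and one of unmoved genes gave p = 0.86. Of 200 simulated dose-responsive genes 182 received a dose, with a median ratio to the true dose of 1.08 and 92.9% within 2-fold, and 20 of 200 flat genes received one.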

Results

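The libraries of 3 cell lines exposed to solvents, a peroxide and a compound called DCA were compared with control wells of the same line. The highest concentrations of DMSO and H2O2 in the human lines had lower median totals than the controls. In Caco-2 the totals at the highest concentration ran from 104205 to 388573 for DMSO and from 48018 to 252575 for H2O2, against 299840 to 1129155 in the controls. In Hep G2 they ran from 98488 to 197223 for DMSO and from 81805 to 319778 for H2O2, against 330150 to 715042. The median totals with MeOH at 10 were 662858 in Caco-2 and 487123 in Hep G2.

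**Figure D1:**
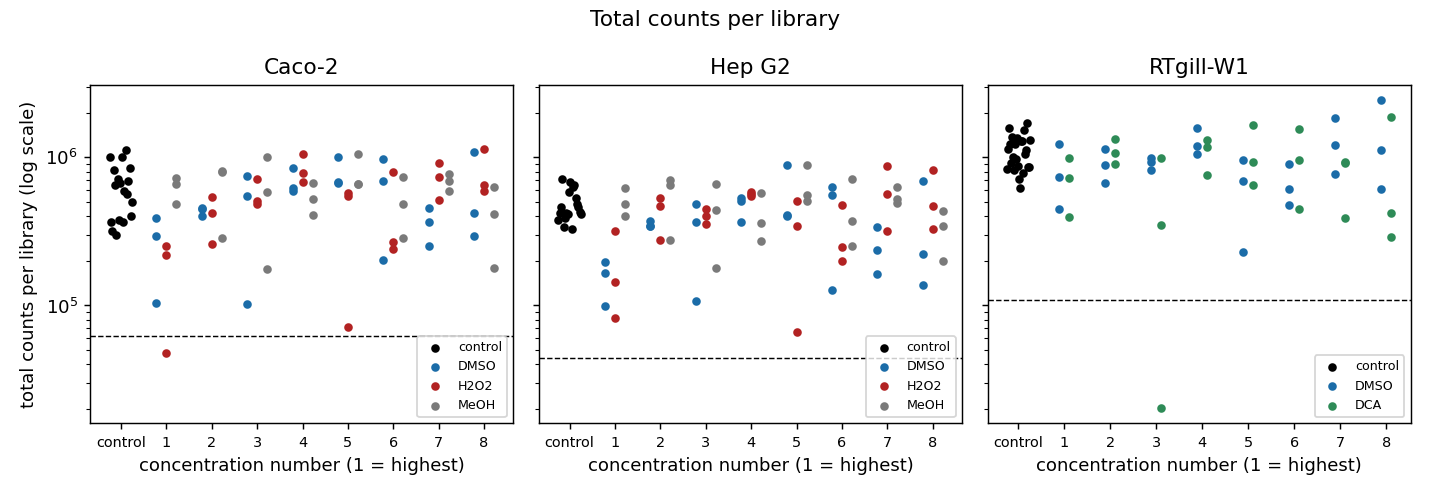
Total counts per library (vertical axis) by concentration, with 1 the highest (horizontal axis), for the chemicals and controls of each line, and dashed lines at 10% of the control median. The control medians were 622199 in Caco-2, 443811 in Hep G2 and 1090943 in RTgill-W1.

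In Caco-2 wells with DMSO at 10, the nuclear receptor gene NR4A2 rose by log2 4.62 ± 0.57, from 2.15 ± 3.27 CPM in 18 control wells to 59.2 ± 40.8 in 3 treated wells (adjusted p = 1e-08). The growth factor gene HBEGF rose from 8.27 ± 4.89 to 76.5 ± 48.5 CPM, the transcription factor gene KLF4 from 14.7 ± 6.52 to 140 ± 23, and the stress-response gene GADD45B from 14 ± 7.29 to 129 ± 45.9 (adjusted p = 3.8e-09, 5.3e-14 and 6.3e-12). ERO1B, which encodes an oxidase of the endoplasmic reticulum, rose by log2 4.08 ± 0.54, and DHRS2, which encodes a dehydrogenase, by 3.34 ± 0.59. The long non-coding genes ARHGEF26-AS1, COPB2-DT, OSER1-DT and SNHG5 rose by log2 4.26, 3.37, 2.85 and 2.79.

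The 10 genes with the largest falls at this concentration all encoded histones, the proteins around which DNA is wound. H2AC13 fell from 1310 ± 148 to 44.6 ± 14.6 CPM, H3C2 from 5140 ± 1220 to 197 ± 110 and H1-2 from 2560 ± 704 to 100 ± 47.6 (adjusted p = 2.6e-21, 6.3e-19 and 9.9e-16, n = 18 and 3). H3C14, H1-3, H3C7, H2AC15 and H3C8 had 0 counts in the treated wells, which makes the falls at least 64.7-fold, 11.8-fold, 8.59-fold, 6.46-fold and 5.33-fold. H2BC7 was 35.5 times lower (interval 9.8 to 293) and H2BC9 25.8 times lower (8.81 to 125).

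Of the fixed lists in these Caco-2 wells, ribosomal protein genes rose most uniformly, with 25 up and 0 down of 27 measured (25 and 0 when adjusted over the list alone, median log2 0.65). RPS18 rose by log2 1.23 ± 0.11, RPL10 by 1.01 and RPL23 by 0.98. The list passed with camera (adjusted p = 9.6e-21), though the adjusted p was 0.068 with an estimated correlation. Mitochondrially encoded genes had 4 up and 0 down of 13 (5 and 0 over the list alone), among them MT-ND4L at log2 1.22, MT-ND4 at 0.91, MT-CO1 at 0.87 and MT-ND1 at 0.62 (camera adjusted p = 0.0013, and 0.35 with an estimated correlation).

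Targets of ATF4, the transcription factor of amino-acid stress, had 4 up and 0 down of 14 in Caco-2 with DMSO (4 and 0 over the list alone). They were ATF3 at log2 2.68, ASNS at 1.7, SLC3A2 at 0.56 and ATF4 itself at 0.42 (camera adjusted p = 0.049, 0.19 with an estimated correlation and 0.056 with the replicate block). Immediate early genes, which respond first to signals, had 3 up and 0 down of 13 (3 and 0 over the list alone): KLF4 at log2 3.21, IER5 at 2.49 ± 0.35 and JUN at 1.3 (adjusted p = 0.045, 0.19 with an estimated correlation and 0.05 with the block). In the unfolded-protein list of the endoplasmic reticulum, DNAJB11 at log2 0.7 and PDIA3 at 0.41 were among 3 genes up, and CANX at −0.41 went the other way, of 17 measured (5 up and 1 down over the list alone, adjusted p = 0.049, 0.35 with an estimated correlation and 0.052 with the block).

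Among genes of cholesterol synthesis 0 were up and 5 down of 22 (0 and 6 over the list alone). HMGCS1 fell from 306 ± 46.9 to 123 ± 26.3 CPM, INSIG1 by log2 0.85 ± 0.14 and FDFT1 by 0.59 (camera adjusted p = 0.049, 0.35 with an estimated correlation and 0.052 with the replicate block). Proliferation genes had 0 up and 7 down of 22 (0 and 9 over the list alone), with MCM3 at log2 −0.97 ± 0.17, TOP2A at −0.75 ± 0.15, CENPF at −0.65 and BUB1 at −0.65 (adjusted p = 0.02, and 0.32 with an estimated correlation). The NRF2 list, of genes that counter oxidants, did not pass (3 up and 1 down of 21, adjusted p = 0.07), nor did enterocyte markers (4 up and 0 down of 11, adjusted p = 0.07), although FTL rose by log2 1.04 and CEACAM5 by 2.51. Targets of p53, heat shock genes, fatty acid synthesis genes and apoptosis regulators did not pass either (adjusted p = 0.78, 0.61, 0.15 and 0.71). They had 1 up and 2 down of 15, 1 and 2 of 18, 0 and 3 of 10, and 0 and 2 of 13. FASN, of the fatty acid list, was at log2 −2.16.

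Lower down the DMSO series in Caco-2, 1.2 was the lowest active concentration, with 1014 genes called (0.6 with the replicate block, with 31). The sestrin gene SESN3 rose there from 95.5 ± 26.3 to 323 ± 22.3 CPM (adjusted p = 9.1e-13), and FGA, ABCA5, KCNJ16 and RRM2B rose by log2 2.31, 2.05, 1.93 and 1.83. The adhesion gene CD44 fell from 136 ± 32.7 to 35.7 ± 3.02 CPM (adjusted p = 2.9e-09). SULT1B1, ANXA13, HMGA1 and SULT1A4 fell by log2 2.76, 2.15, 2.11 and 1.81.

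Across all concentrations of DMSO in Caco-2, 4155 of 8215 genes passed the any-dose test. At 10 there were 497 genes up and 584 down (550 and 518 with RLE factors, and 564 and 530 with DESeq2), and at 5 there were 1993 up and 1940 down. Going down from 10 the totals were 1081, 3933, 2609, 1014, 19, 5, 16 and 2 genes. The tPOD was 0.366 (interval 0.249 to 0.388, from 946 genes with a dose of 3885 entered), and 2522 genes gave no dose because of a poor fit of the curves. It was 0.13 for the 25th lowest gene and 1.09 with a response of 2 SD.

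**Figure D2:**
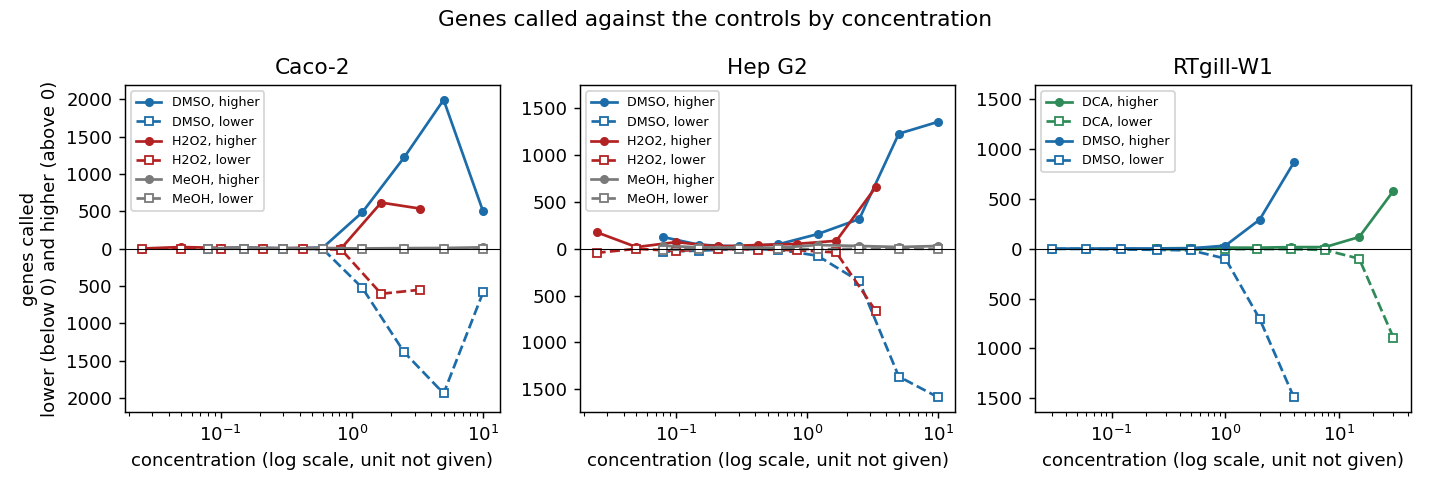
Genes called higher (above 0) and lower (below 0) than in the controls (vertical axis) at each concentration (horizontal axis), by line and chemical. The largest totals were 3933 in Caco-2, 2936 in Hep G2 and 2353 in RTgill-W1.

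In Caco-2 with H2O2 at 3.33, where 2 wells had enough counts, the cytochrome P450 gene CYP1A1 rose from 3.83 ± 3.24 CPM to 40.8 ± 1.3 (n = 18 and 2, log2 3.3 ± 0.65, adjusted p = 0.00021). ATF3, a stress-induced transcription factor gene, rose from 8.18 ± 4.52 to 62.1 ± 24.3 CPM and HBEGF from 8.14 ± 4.8 to 60.4 ± 14.9 (adjusted p = 7.1e-06 and 1.7e-05). EPS8L3, MAPK8IP3, KMT2B, FOSL1, PLEC, NPIPB12 and UCA1 rose by log2 3.5, 3.35, 2.95, 2.84, 2.77, 2.69 and 2.48. The urea-cycle gene CPS1 and the genes ALKBH6 and CCDC92 had 0 counts in the treated wells and were at least 3.67-fold, 3.79-fold and 3.78-fold lower. The steroid sulfatase gene STS was 17.2 times lower (interval 3.08 to 682), NFKB1 12.5 times lower (2.24 to 497) and FREM2 12.1 times lower (2.15 to 478).

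NRF2 targets rose in these Caco-2 wells with 11 up and 1 down of 22 (12 and 1 over the list alone). SQSTM1 rose by log2 1.61 ± 0.23, GCLM by 1.6, TXNRD1 by 1.24 and FTL by 1.11, while ME1 fell by 1.08 ± 0.19 (camera adjusted p = 7.5e-06, and 0.03 with an estimated correlation). ATF4 targets had 8 up and 0 down of 16 (8 and 0 over the list alone), with the amino-acid transporter gene SLC3A2 at log2 1.8 ± 0.2, ASNS at 2.46, ATF3 at 2.92 and ATF4 at 0.87 (adjusted p = 0.00019, and 0.0097 with an estimated correlation). Immediate early genes had 5 up and 0 down of 15 (6 and 0 over the list alone): FOSL1, DUSP1 at log2 1.98, KLF4 at 1.91 and JUN at 1.43 were among them (adjusted p = 0.00086, and 0.046 with an estimated correlation).

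Mitochondrially encoded genes rose under H2O2 in Caco-2 in 12 of 13 cases (12 over the list alone, median log2 1.4), with MT-ND4 at 2.03 and MT-ATP6 at 1.92 (adjusted p = 7e-14, and 0.03 with an estimated correlation). Ribosomal protein genes had 24 up and 0 down of 27 (25 and 0 over the list alone), with RPS18 at log2 1.5 and RPS6 at 1.23 (adjusted p = 1.8e-27, and 0.013 with an estimated correlation). Heat shock genes were mixed. HSP90AB1 at log2 1.06 ± 0.12, AHSA1 at 1.24 and DNAJA1 at 0.54 were among 4 up, and HSPA4L at −1.41 and HSP90AA1 at −0.63 were the 2 down, of 18 (5 up and 2 down over the list alone, adjusted p = 0.038, and 0.17 with an estimated correlation). Cholesterol synthesis, proliferation, junction and actin genes did not pass (adjusted p = 0.076, 0.076, 0.092 and 0.064), while PCNA moved by log2 −1.16, KRT19 by 1.37 and ACTB by 1.1.

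At the next concentration of H2O2 in Caco-2, 1.67, which was the lowest active one (0.83 with the replicate block), FOS rose from 3.18 ± 2.67 to 34.1 ± 1.91 CPM and KLF4 from 14.5 ± 6.41 to 108 ± 21.4 (adjusted p = 2.7e-06 and 5.1e-12, n = 18 and 3). NR4A2, RYR3 and HBEGF rose by log2 3.37, 3.12 and 2.91. The sulfotransferase gene SULT1B1 had 0 counts there and was at least 10.6-fold lower, and RNF157, CLSTN2, SLC38A4 and H2AC7 fell by log2 2.59, 2.44, 2.41 and 2.37. Over the series 922 of 8405 genes passed the any-dose test, with 535 up and 551 down at 3.33 (637 and 458 with RLE factors, and 673 and 384 with DESeq2) and 616 up and 605 down at 1.67. From 0.83 downward the totals were 19, 6, 5, 9, 22 and 1. The tPOD was 0.563 (interval 0.396 to 0.608, from 518 of 823 genes). It was 0.257 for the 25th lowest gene, 0.952 with a response of 2 SD and 0.375 without the highest concentration. Without replicate numbers 1 and 3, which leaves 1 well at 3.33, it was 0.239 and 0.261.

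With MeOH at 10, the small heat shock protein gene CRYAB rose in Caco-2 from 0.448 ± 0.849 to 31.9 ± 13.2 CPM, a 43.7-fold change (adjusted p = 1.3e-08, n = 18 and 3). The aldo-keto reductase genes AKR1C2 and AKR1C1 rose from 113 ± 22.8 to 296 ± 43.7 CPM and from 445 ± 112 to 898 ± 154 (adjusted p = 1.3e-07 and 0.00012). SNHG1, SLC38A9 and H2BC4 rose by log2 1.27, 0.96 and 0.91, and the glutamate dehydrogenase gene GLUD1 was the only gene to fall, from 1080 ± 146 to 761 ± 123 CPM (adjusted p = 0.041). The NRF2 list had 3 up and 0 down of 22 (4 and 0 over the list alone), the 2 reductases and SQSTM1 at log2 0.73 (camera adjusted p = 1e-04, and 0.086 with an estimated correlation). Ribosomal protein genes passed with a median of log2 0.21 and 0 single genes called of 27 (4 up over the list alone, adjusted p = 9.1e-08, and 0.44 with an estimated correlation). In all, 25 of 8252 genes passed the any-dose test, 17 were up and 1 down at 10, and no concentration met the rule for an active one. With the replicate block 73 genes were called at 10 and 24 at 5, so that both met the rule. The tPOD of 0.016 (interval 0.0117 to 0.0256, from 15 of 20 genes) lay below the lowest concentration. The median gene dose, 0.0295, did too, so the value does not separate a response to dose from an offset between controls and treated wells.

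Among genes with counts in the controls, HBEGF had the largest rise in Hep G2 with DMSO at 10, from 2.3 ± 2.3 CPM in 18 control wells to 617 ± 127 in 3 treated wells (236-fold, adjusted p = 9.7e-28). WDR47 rose from 6.88 ± 3.49 to 508 ± 105 CPM, ATF3 from 5.17 ± 5.31 to 248 ± 90.2 and BCL2L11, which encodes a trigger of apoptosis, from 5.88 ± 4.16 to 183 ± 56.5 (adjusted p = 1.6e-27, 1.2e-16 and 7e-16). The nuclear receptor gene NR4A3 rose by log2 6.67 ± 0.59, MYLIP by 5.92 ± 0.4, RGS2 by 4.85, LINC00910 by 4.72 and SESN2 by 4.59 ± 0.39. PLCL1 had 0 counts in the controls and was at least 111-fold higher. Among falling genes, NHLRC2, H2BC7, FMC1-LUC7L2, TOE1, NOL4L and PLPP6 had 0 counts in the treated wells and were at least 7.92-fold, 7.81-fold, 7.12-fold, 6.11-fold, 5.37-fold and 5.37-fold lower. The thyroid hormone receptor gene THRB, the bile-acid synthesis gene AKR1D1, the fatty acid elongase gene ELOVL6 and RMI1 were at least 5.02-fold, 4.95-fold, 4.54-fold and 4.13-fold lower.

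Mitochondrially encoded genes rose in all 12 measured cases in these Hep G2 wells (12 over the list alone, median log2 2.28), with MT-ATP6 at 2.9 and MT-ND4 at 2.66 (camera adjusted p = 4.5e-14, and 0.053 with an estimated correlation). Ribosomal protein genes had 25 up and 0 down of 27 (25 and 0 over the list alone), with RPS18 at log2 1.24 and RPL5 at 1.17 (adjusted p = 1.1e-10, and 0.089 with an estimated correlation). Genes of hepatocyte function had 16 up and 0 down of 23 (16 and 0 over the list alone), among them the plasma protein genes FGB at log2 1.33, AMBP at 1.22, AHSG at 1.11 and SERPINA1 at 1.04 (adjusted p = 0.00034, and 0.42 with an estimated correlation).

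With DMSO in Hep G2, 5 stress lists passed upward with the preset correlation and 0 with an estimated one. The unfolded-protein list had 12 up and 1 down of 17 (13 and 1 over the list alone): PDIA3 at log2 1.81 ± 0.18, DNAJC3 at 1.74 and the chaperone gene HSPA5 at 1.51 ± 0.17 rose, while the transcription factor gene XBP1 fell by 2.53 ± 0.24 (adjusted p = 2.4e-05, and 0.13 with an estimated correlation). ATF4 targets had 8 up and 1 down of 12 (8 and 1 over the list alone), with ASNS at log2 3.6, SLC3A2 at 1.92 and ATF4 at 1.57 ± 0.13, against PHGDH at −1.93 (adjusted p = 0.012, and 0.053 with an estimated correlation). Targets of p53 had 7 up and 1 down of 17 (7 and 1 over the list alone): the growth-arrest gene GADD45A at log2 3.87 ± 0.2, SESN2 at 4.59, POLH at 2.26 and PPM1D at 1.73, against XPC at −2.17 (adjusted p = 0.023, and 0.089 with an estimated correlation). Immediate early genes had 6 up and 1 down of 11 (6 and 1 over the list alone), with IER5 at log2 3.69, EGR1 at 3.61, CCN1 at 3.25 and IER3 at 2.13, against MYC at −1.54 (adjusted p = 0.0071, and 0.053 with an estimated correlation). Heat shock genes had 7 up and 4 down of 17 (7 and 4 over the list alone). HSPH1 at log2 1.88 and HSP90AB1 at 1.15 rose, whereas HSPA8, HSPE1, HSPD1 and HSP90AA1 fell by 0.82, 0.8, 0.41 and 0.4 (adjusted p = 0.038, and 0.3 with an estimated correlation).

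Several lists with many called genes did not pass as lists in Hep G2 with DMSO. Cholesterol synthesis had 1 up and 8 down of 17 (adjusted p = 0.06), with HMGCS1 at log2 −3.3 and FDFT1 at −2.67 against IDI1 at 0.74, and proliferation had 1 up and 10 down of 21 (adjusted p = 0.06), with MCM3 at −1.47 against PCNA at 1.33. PPARA targets had 0 up and 6 down of 11 (adjusted p = 0.06). The NRF2 list was split with 5 up and 4 down of 20 (adjusted p = 0.7), where GCLC moved by log2 1.94 and FTL by 1.19, and AKR1C1 by −2.55 and AKR1C2 by −1.52.

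In total 3306 of 7164 genes passed the any-dose test for DMSO in Hep G2, with 1351 up and 1585 down at 10 (1465 and 1412 with RLE factors, and 1500 and 1184 with DESeq2). The median log2 fold change of all genes at 10 was −0.167 with TMM and −0.0903 with RLE factors. Totals from 10 downward were 2936, 2587, 664, 230, 56, 27, 63 and 156, so that every concentration met the rule for an active one. At the lowest, 0.08, GAS5 rose from 117 ± 44.4 to 405 ± 106 CPM (adjusted p = 2.5e-06), NIPAL2, ACSM2A, SCARNA9 and SLC37A3 rose by log2 1.74, 1.62, 1.51 and 1.5, and ANKRD40, SNRPD3, HNRNPUL2-BSCL2, GINS1 and OTUB1 fell by 1.5, 1.49, 1.34, 1.21 and 1.16. With replicate blocks 1 and 2 only, an alternative added after the data were seen, the total at 0.08 was 5. The tPOD was 0.456 (interval 0.314 to 0.681, from 1662 of 3108 genes). It was 0.0216 for the 25th lowest gene, 1.7 with a response of 2 SD, 0.207 without replicate number 1, 0.0791 without the highest concentration and 0.255 with the doses of the treatment field.

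For H2O2 at 3.33 in Hep G2, the genes at displaced places in the deposited table were left out, a choice made after the data were seen. The insulin-like growth factor binding protein gene IGFBP1 rose from 46.8 ± 17.8 to 1010 ± 323 CPM (adjusted p = 1.5e-25, n = 18 and 3). FOS, an immediate early gene, rose from 0.0889 CPM to 64.4 ± 9.89, a ratio of 507 (interval 84.5 to 20700). The matrix protease gene MMP3 rose by log2 5.66 ± 0.47, MYT1L by 5.32, HBEGF by 4.8 ± 0.5, RGS2 by 4.73, TTN by 4.62, KLF4 by 4.45 and ATF3 by 4.28. H3C15 fell from 1970 ± 299 to 109 ± 59.3 CPM and H2AC17 by log2 3.24 ± 0.33 (adjusted p = 3.1e-19 and 3.1e-11). H2BC10 and SCRN3 had 0 treated counts and were at least 3.98-fold and 3.59-fold lower, and ACOT1, H2BC7, H2AC15, H2BC13, TADA3 and AKR1D1 were 33.5, 15.8, 14, 11.2, 10.5 and 10 times lower (intervals 5.98 to 1320, 4.36 to 131, 2.49 to 556, 3.81 to 54.4, 1.86 to 418 and 2.75 to 83.2).

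NRF2 targets rose in these Hep G2 wells with 15 up and 0 down of 21 (15 and 0 over the list alone). The thioredoxin reductase gene TXNRD1 rose from 125 ± 20.5 to 630 ± 114 CPM, SLC7A11 by log2 2.65, SQSTM1 by 2.21 and GCLM by 1.71 (camera adjusted p = 1.2e-09, and 0.0032 with an estimated correlation). Immediate early genes had 11 up and 0 down of 12 (11 and 0 over the list alone, median log2 2.67), with EGR1 at 3.69, JUN at 3.26 ± 0.29 and IER3 at 2.13 (adjusted p = 2.3e-16, and 3.9e-09 with an estimated correlation). ATF4 targets had 8 up and 1 down of 12 (9 and 1 over the list alone), with PPP1R15A at log2 4.05, ASNS at 2.88 and ATF4 at 0.81, against PHGDH at −1.68 (adjusted p = 0.00024, and 0.006 with an estimated correlation). Heat shock genes had 12 up and 0 down of 17 (12 and 2 over the list alone), including DNAJB4 at log2 2.16, the co-chaperone gene BAG3 at 1.94, HSPH1 at 0.89 and HSP90AB1 at 0.72 (adjusted p = 5.9e-05, and 0.014 with an estimated correlation).

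Targets of p53 under H2O2 in Hep G2 had 6 up and 2 down of 17 (8 and 2 over the list alone). GDF15 at log2 2.58 ± 0.15, GADD45A at 2.89, the cell-cycle inhibitor gene CDKN1A at 3.27 and MDM2 at 0.69 went up, and CCNG1 at −0.7 and SESN1 at −0.99 went down (camera adjusted p = 0.016, and 0.17 with an estimated correlation). The unfolded-protein list had 6 up and 0 down of 17 (6 and 0 over the list alone), with PDIA3 at log2 0.98 and HSPA5 at 0.9 (adjusted p = 0.027, and 0.44 with an estimated correlation). Targets of actin signalling had 5 up and 1 down of 13 (5 and 1 over the list alone): CCN1 at log2 2.98 and THBS1 at 0.9 were among those up, against TPM4 at −0.44 (adjusted p = 0.03, and 0.24 with an estimated correlation). Lists past the threshold downward were cholesterol synthesis, with 0 up and 7 down of 19 (0 and 8 over the list alone, ACAT2 at log2 −1.85, HMGCS1 at −1.35, FDFT1 at −1.02), and proliferation, with 0 up and 6 down of 21 (0 and 10 over the list alone, MCM3 at −1.14, CENPF at −0.98, PCNA at −0.87, TOP2A at −0.85). Their adjusted p was 0.00085 and 0.00015, and 0.037 and 0.037 with an estimated correlation. Ribosomal protein genes (6 up and 6 down of 27) and hepatocyte genes (2 up and 3 down of 23) did not pass (adjusted p = 0.48 and 0.88).

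**Figure D3:**
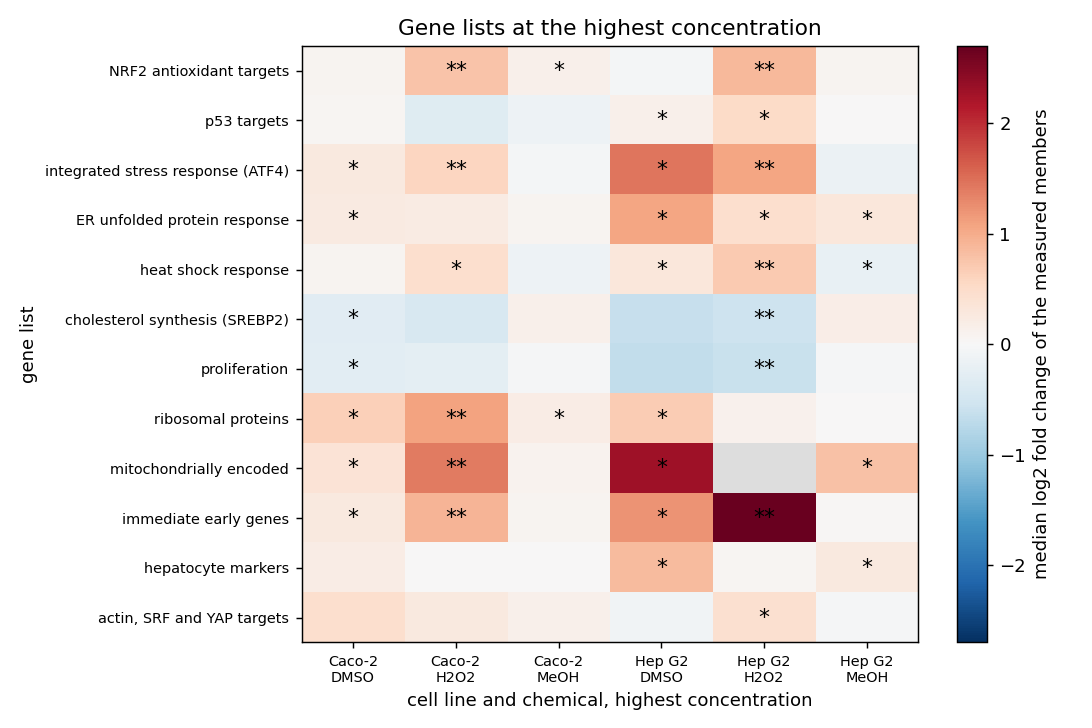
Median log2 fold change (colour) of each gene list past the threshold in at least 1 comparison (vertical axis) at the highest concentration of each human line and chemical (horizontal axis), with grey where a list was not measured. An asterisk marks lists past the threshold with the preset correlation and a double asterisk those also past it with an estimated correlation, such as immediate early genes under H2O2 in Hep G2 (median log2 2.67).

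The any-dose test for H2O2 in Hep G2 passed 1094 of 7027 genes, with 653 up and 663 down at 3.33 (671 and 650 with RLE factors, 676 and 533 with DESeq2, and 1085 and 793 without a filter on low counts). With the counts as deposited these were 1345, 671 and 923, and with the counts re-sorted 1129, 605 and 747. Totals from 1.67 downward were 124, 67, 48, 26, 94, 18 and 218, and with replicate blocks 1 and 2 only they were 43, 4, 3, 7, 7, 1 and 2. At 0.1, the lowest concentration to meet the rule (0.025 with the replicate block), SNHG1 rose by log2 2.05, GAS5 from 120 ± 45.9 to 366 ± 126 CPM (adjusted p = 8.1e-06), SCARNA9 by 1.42, HMGN5 by 1.32 and TMEM161B-DT by 1.22. ARHGEF10L was 11.1 times lower (interval 3.03 to 92), and ABHD4, PRXL2C, MKRN2 and PAK1IP1 fell by log2 1.74, 1.66, 1.52 and 1.42. The tPOD of 0.0136 (interval 0.00824 to 0.148, from 475 genes with a dose) lay below the lowest concentration. It was 1.31 with a response of 2 SD and 0.00553 with the doses of the treatment field. The median gene dose, 1.68, lay within the concentrations given. The tPOD rests on the lowest gene doses, so it does not separate a response to dose from an offset between controls and treated wells.

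**Figure D4:**
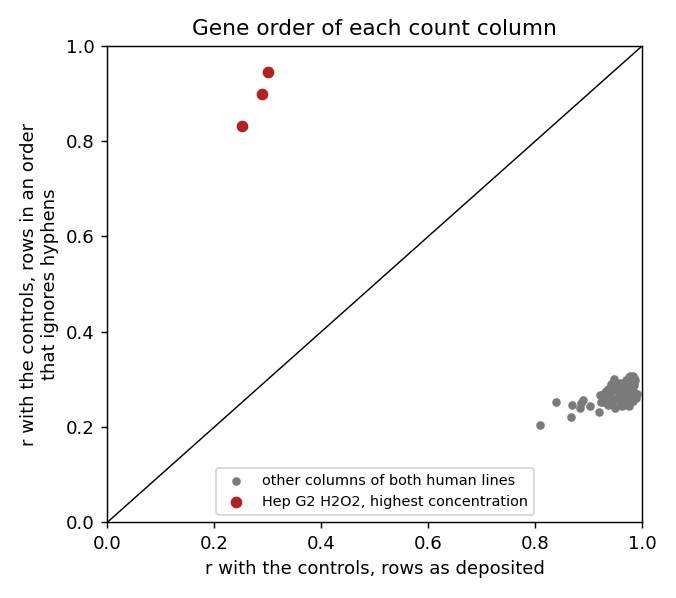
Correlation r with the controls over the genes at differing places, in the gene order as deposited (horizontal axis) and in the order that ignores hyphens (vertical axis), for each Hep G2 and Caco-2 library. The 3 libraries of the highest H2O2 concentration in Hep G2 (red) had at most 0.3 in the first and at least 0.832 in the second.

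Mitochondrially encoded genes were higher than in the controls in Hep G2 with MeOH at 10, with 7 up and 0 down of 12 (12 and 0 over the list alone). MT-ND3 rose from 74.6 ± 22.1 to 162 ± 32.7 CPM (adjusted p = 0.00097), MT-ND1 by log2 0.85, MT-ND5 by 0.82 and MT-CO2 by 0.81 (camera adjusted p = 1.1e-16, and 0.12 with an estimated correlation). Their mean share of the counts was 1.74% there and 1.15% in the controls, but also 1.65%, 1.7% and 1.72% at the lowest concentrations of MeOH, DMSO and H2O2. The stress hormone gene GDF15 rose from 98.9 ± 15.2 to 187 ± 32.6 CPM and the spectrin gene SPTBN1 from 394 ± 83.9 to 700 ± 54.9 (adjusted p = 0.00025 and 0.00025), with FSTL3, GAS5 and H2AC21 at log2 1.18, 1.1 and 0.92. HIGD1A, PM20D2 and the superoxide dismutase gene SOD2 fell by log2 1.42 ± 0.33, 1.13 ± 0.23 and 0.61 ± 0.15. The unfolded-protein and hepatocyte lists passed upward with 0 single genes called of 17 and 23 (3 and 6 up over the list alone, adjusted p = 0.00015 and 6.4e-05, and 0.46 and 0.68 with an estimated correlation). The heat shock list passed downward, again with 0 of 17 (0 over the list alone, median log2 −0.19, adjusted p = 0.018, and 0.46 with an estimated correlation). Over the series 85 of 7172 genes passed the any-dose test, and 28 were up and 3 down at 10, the lowest active concentration. With the replicate block every concentration met the rule, with 102 genes at 10 and 130 at 0.08. With replicate blocks 1 and 2 only, 0 genes were called at 10. The tPOD was 0.013 (interval 0.0104 to 0.0223, from 36 genes), below the lowest concentration. The median gene dose, 0.0238, was below it too, and the highest was 0.107. The value therefore does not separate a response to dose from an offset between controls and all treated wells.

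The muscle filament gene TTN had the largest difference toward Hep G2 between the human lines at the highest DMSO concentration, falling by log2 2.45 in Caco-2 and rising by 4.2 in Hep G2 (difference 6.64 ± 0.53, adjusted p = 2.8e-15). ZNF264 also moved in opposite directions, by log2 −3.3 in Caco-2 and 1.45 in Hep G2, and STK17B by −0.78 and 3.15. ZNF264 had only 2 counts in the treated Caco-2 wells, so its fitted change there is uncertain. HBEGF rose in both lines but more in Hep G2 (log2 3.27 and 7.92). THRB, NHLRC2, NOL4L, MORC4 and RMI1 had 0 counts in the treated Hep G2 wells and 34.6 ± 11.2, 31.5 ± 18.7, 67.6 ± 10.3, 64.5 ± 22.3 and 38.3 ± 18.7 CPM in Caco-2. Of 7813 genes tested, 893 had a higher and 814 a lower change in Hep G2. With RLE factors these were 858 and 895, and DESeq2 called 1682. For Hep G2 the treatment field gives 5.46 as this concentration, against 10 in Caco-2.

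Under H2O2 the largest line differences toward Hep G2 were in CPS1, which had 0 counts in the treated Caco-2 wells, SDR42E1 (log2 −0.38 in Caco-2 and 5.01 in Hep G2), CCDC144A (−1.56 and 3.65), RGS2 (0.92 and 4.69) and the transcription factor gene KLF5 (−0.51 and 2.91, adjusted p = 2e-10). Lower in Hep G2 were SCRN3, with 0 counts there, MAD2L2 (1.34 and −2.38, the latter from only 2 treated counts), KLC4 (1.52 and −2.15), the apolipoprotein gene APOC3 (1.37 and −1.9) and H4C15 (0.87 and −2.3). These were among 150 genes with a higher and 242 with a lower change of 8222 tested (210 and 364 with the counts as deposited, and 370 in total with DESeq2). The treatment field gives 1.88 for these Hep G2 wells and 3.33 for Caco-2. For MeOH 0 of 7978 genes differed between the lines, with edgeR and with DESeq2, and 491 had an unadjusted p under the threshold.

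Set against MeOH at the highest concentration of both, DMSO in Caco-2 gave higher HBEGF (75.5 ± 48.4 against 4.23 ± 3.63 CPM), GADD45B (127 ± 45.6 against 10 ± 2.37), NR4A2, ARHGEF26-AS1 and ERO1B (adjusted p = 2.8e-05, 3e-06, 0.0016, 0.023 and 0.0029). H3C14, H1-3, H2AC15, H3C8 and H3C7 had 0 counts with DMSO and 597, 98, 76, 58 and 54 with MeOH. In Hep G2, HBEGF was at 606 ± 124 CPM with DMSO and at 1.28 ± 1.14 with MeOH, ATF3 at 243 ± 88.9 and 3.41 ± 2.96, and NR4A3, BCL2L11 and the cyclin gene CCNE2 were higher by log2 6.3, 6.22 and 5.73. With MeOH, HBEGF, NR4A3, BCL2L11 and CCNE2 had only 2, 1, 3 and 1 counts, so the size of these differences is uncertain. H2BC7, FMC1-LUC7L2, NHLRC2, THRB and PLPP6 had 0 counts with DMSO. In all 151 genes were higher and 262 lower of 8665 in Caco-2, and 1058 higher and 1307 lower of 7460 in Hep G2. For Hep G2 the treatment field gives 5.46 for DMSO and 10 for MeOH. With DESeq2 the numbers were 214 and 227 in Caco-2 and 1173 and 874 in Hep G2. With RLE factors they were 198 and 219, and 1191 and 1088.

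In the trout gill line with DCA at 30, the gene ENSOMYG00000021413 rose from 28.5 ± 12.9 CPM in 24 control wells to 954 ± 262 in 3 treated wells (log2 5.07 ± 0.28, adjusted p = 4.8e-21) and ENSOMYG00000077667 by log2 5.05. ENSOMYG00000053905 and ENSOMYG00000010168 had 0 treated counts and were at least 31.9-fold and 15.4-fold lower. Of 16529 genes 630 passed the any-dose test (1612 with the replicate block), with 578 up and 892 down at 30 (864 and 1294 with the block, 728 and 791 with RLE factors, and 949 and 837 without a filter on low counts) and 116 up and 101 down at 15. The median log2 fold change at 30 was −0.173 with TMM and −0.0842 with RLE factors. The lowest active concentration was 3.8, where 20 genes were called. With the block every DCA concentration met the rule, the lowest being 0.25 with 55 genes. The tPOD was 1.72 (interval 0.662 to 2.22, from 430 genes). It was 1.23 with the block, 0.108, 0.628 and 0.126 without replicate numbers 1, 2 and 3, and 0.21 without the highest concentration. For the 25th lowest gene it was 0.422, and with a response of 2 SD it was 5. With the other dose order of the treatment field it was 0.0408, from 33 genes.

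DMSO at 4 raised ENSOMYG00000023353 in the trout line from 1.98 ± 2.02 to 59.7 ± 20.4 CPM (adjusted p = 6.9e-08, n = 24 and 3) and ENSOMYG00000036468 by log2 4.77. ENSOMYG00000063370 and ENSOMYG00000033076 had 0 treated counts and were at least 55.1-fold and 38.8-fold lower. The any-dose test passed 1326 of 15374 genes (2381 with the replicate block), and 863 were up and 1490 down at 4 (1176 and 1926 with the block, 1178 and 1267 with RLE factors, and 1804 and 1476 without a filter on low counts). The median log2 fold change at 4 was −0.0327 with TMM and 0.1 with RLE factors. At 2 there were 290 up and 704 down. The lowest active concentration was 0.5, with 20 genes, and with the block it was 0.12, with 30 genes. The tPOD was 0.134 (interval 0.0963 to 0.224, from 1008 genes). It was 0.124 with the block and 0.0443 to 0.118 with each replicate number left out in turn. For the 25th lowest gene it was 0.0277, and with a response of 2 SD it was 0.517. It was 0.0795 without the highest concentration, and 0.0068 from 64 genes with the other dose order of the treatment field.

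**Figure D5:**
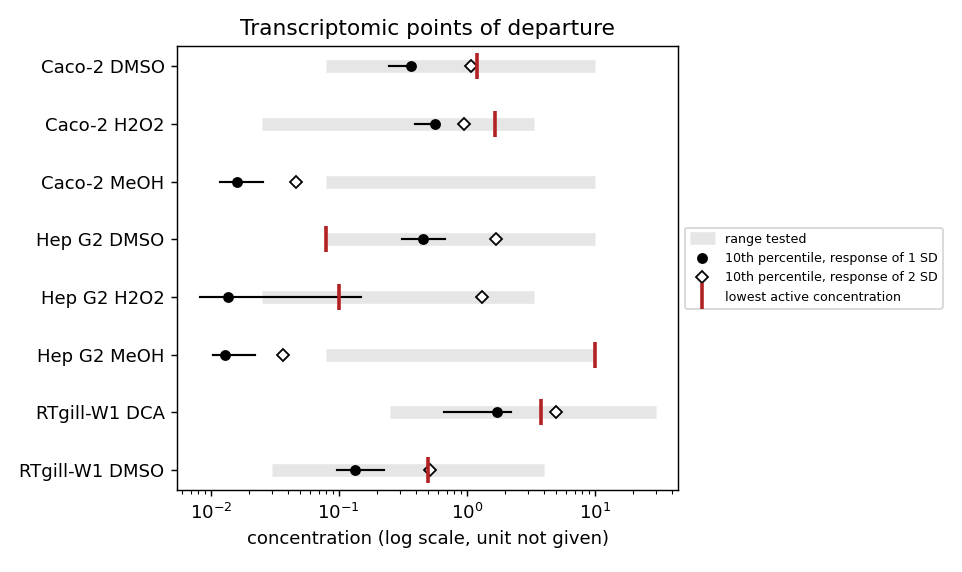
Transcriptomic point of departure with its interval (filled points; horizontal axis, unit not given) for each line and chemical (vertical axis), with the range of concentrations given (grey), the value for a response of 2 SD (open points) and the lowest active concentration (red). The filled points ran from 0.013 for MeOH in Hep G2 to 1.72 for DCA in RTgill-W1. Those for MeOH in both human lines and for H2O2 in Hep G2 lay below the lowest concentration given and are extrapolated.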

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

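A difference between the human lines set apart 1707 genes under DMSO and 392 under H2O2 at the highest concentration, and the line-by-treatment tests behind these counts were chosen before the data were seen. Under DMSO the Hep G2 minus Caco-2 log2 difference was 6.64 for TTN, 4.75 for ZNF264, 4.65 for HBEGF, 4.53 for RND3 and 3.93 for STK17B. It was −7.44 for THRB, −7.17 for NHLRC2, and −6.49 for NOL4L, MORC4 and RMI1, genes with 0 counts in the treated Hep G2 wells, so that these values are fitted and not bounds. The treatment field gives lower top doses in Hep G2 (5.46 for DMSO and 1.88 for H2O2) than in Caco-2 (10 and 3.33), so a difference in dose is not excluded as a part of these differences. Fitted values also stand under H2O2 for CPS1, with 0 counts in the treated Caco-2 wells, and SCRN3, with 0 in the treated Hep G2 wells. Only 2 counts stood behind ZNF264 under DMSO in the treated Caco-2 wells and MAD2L2 under H2O2 in the treated Hep G2 wells. Under H2O2 the Hep G2 minus Caco-2 log2 difference was 6.17 for CPS1, 5.39 for SDR42E1, 5.21 for CCDC144A, 3.77 for RGS2 and 3.42 for KLF5. The differences of the other sign were −6.05 for SCRN3, −3.72 for MAD2L2, −3.67 for KLC4, −3.28 for APOC3 and −3.17 for H4C15.

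Mitochondrially encoded genes drew attention in the deposited counts of the highest H2O2 concentration in Hep G2, and both tests of this pattern were chosen after it was seen. As deposited, all 12 of these genes fell, with a median log2 fold change of −8.95. If the counts stand in another gene order, the displaced genes should correlate with the controls once that order is applied, and r of the 3 wells rose from between 0.251 and 0.3 to between 0.832 and 0.946, while the other 177 columns had at most 0.308 under that order. If mitochondrial transcripts were lost, the fall should remain, but with the counts re-sorted the median was 2.33 and all 12 genes rose. The gene order therefore accounts for the fall, and a loss of mitochondrial transcripts does not.

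Genes called at the lowest H2O2 concentration in Hep G2 formed the next pattern, with 173 up and 45 down, and of its tests the contrast with MeOH was set before the data were seen and the one on block 3 after. The contrast of the lowest H2O2 with the lowest MeOH concentration called 0 genes. By the prediction as first written, 0 would have excluded an effect of the chemical, but that prediction compared 3 with 3 wells to 218 calls from 3 against 18. A check of its power was added after the 0 was seen: with 3 control wells in place of the MeOH wells the contrast called a median of 15.5 genes over 100 draws (0 to 314), under 10% of the 218 in 59 draws and 0 in 13. The other contrasts between 2 chemicals at the 2 lowest concentrations in Hep G2 also called 0 genes. So no difference between the chemicals was found there, but under 10% of the calls can arise from 3 against 3 wells even where a difference exists, and the contrast cannot decide. Without replicate block 3, controls included, 2 genes were called (125 without block 1 and 217 without block 2), and the lowest DMSO and MeOH concentrations had 5 and 0 instead of 156 and 45. The number of calls at the lowest concentrations in Hep G2 therefore depends on block 3, and the calls could come from controls and treated wells lying apart there.

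Fewer genes were called at 10 than at 5 of DMSO in Caco-2, and of the tests of this pattern the one on depth was set before the data were seen and the one on dose after. With every library above 104205 counts, the lowest total at 10, thinned to that number, 1588 genes were called at 5 and 584 at 10, so that lower depth does not account for the pattern. A lower dose of the same series at 10 should move genes in the same direction as at 5, but 29.9% of the 643 genes called at both had opposite signs (192 genes). With separate control wells for each contrast 30.9% of 530 did. How often signs differ between other concentrations of the series was not tested, so this cannot exclude a lower dose at 10. Of the genes called at both, 198 were up and 253 down at both, against 121 and 138 by independent lists. A direct contrast of 10 with 5 called 2816 genes.

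Regrouping the wells at random was the last check, chosen before the data were seen for the human lines and after for RTgill-W1, and the number of splits was raised to 100 for all results after an early draw for MeOH in Hep G2 held a split with more genes than the real grouping. Each value here is the number of splits, the real one included, with as many genes as the real grouping. In Caco-2 it was 1 of 100 for any dose of DMSO (4155 genes, and at most 743 in another split), 1 for H2O2 (922, 180) and 1 for MeOH (25, 7), and at the highest concentration 1 (1081, 248), 1 (1086, 17) and 2 (18, 254). In Hep G2 it was 1 for any dose of DMSO (3306, 202), 1 for H2O2 (1094, 52) and 1 for MeOH (85, 6), and at the highest concentration 1 (2936, 965), 1 (1316, 243) and 1 (31, 16). For line differences it was 1 for DMSO (1707, 150), 1 for H2O2 (392, 40) and 100 for MeOH, where the real grouping had 0 genes and another split 219. The early split with more genes for MeOH in Hep G2 is not among the 100. The values for MeOH in Hep G2 therefore understate how often a random split calls as many genes. Splits in the human lines were not made within replicate blocks.

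Only 10 splits exist for DMSO against MeOH, too few to reach the threshold. There 1 split in Caco-2 (413 genes, and at most 2 in another) and 1 in Hep G2 (2365, 35) had as many genes as the real one. In RTgill-W1 it was 1 of 100 for any dose of DCA (630, 74) and 1 for DMSO (1326, 19), and at the highest concentration 1 (1470, 1) and 1 (2353, 1). With splits within replicate blocks it was 1 (at most 17 in another) and 1 (14) for any dose, and 1 (36) and 1 (121) at the highest concentration.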

How the results depend on the processing

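Of the genes named by the size of their change, none changed direction in an alternative that gave it an adjusted p. They had been chosen for large changes with every treated well on the same side, so a turn was unlikely. Other list members named here were not followed through the alternatives. No list past the threshold changed direction with the replicate block. With RLE factors, the list medians of NRF2 targets and of glycolysis genes for DMSO in Hep G2, which did not pass, moved from −0.0435 to 0.0319 and from −0.0487 to 0.0277. Which direction held more genes did change for some results. With RLE factors and with DESeq2, more genes were up than down at the highest concentration for DMSO and H2O2 in both human lines (550 up and 518 down, 637 and 458, 1465 and 1412, and 671 and 650 with RLE factors) and more were higher with DMSO than with MeOH in Hep G2 (1191 and 1088). The line difference under DMSO turned to more genes lower in Hep G2 with RLE factors (858 and 895) and without each replicate number (529 and 619, 501 and 630, and 668 and 801). Without a filter on low counts, H2O2 in Hep G2 had 1085 up and 793 down, DCA 949 and 837, and DMSO in RTgill-W1 1804 and 1476. Of the comparisons of single genes at a concentration with each alternative, 1586 kept their call and 207 lost it, and for genes of the differences these numbers were 274 and 40. Comparisons in which the gene got no adjusted p were left out. With DESeq2, 116 genes at a concentration kept their call and 6 lost it, against 151 and 1 with the replicate block. For gene lists, which were tested again only with an estimated correlation and with the block, 232 stayed on the same side of the threshold, 29 lost their call and 3 gained one. The values below are counts that moved by over 1.5 times, tPODs that moved, and calls that ended. The cause was not tested unless it is named. Depth limits these data: the median totals at the highest concentrations of DMSO, H2O2 and DCA were below those of the controls, and 0 counts in 2 or 3 treated wells bound a fold change only from 1 side. Wells of DMSO and MeOH at the highest concentration shared a plate row and differed in 413 genes in Caco-2 and 2365 in Hep G2, so the row alone does not account for the response to DMSO.

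With the plate row as a covariate, the genes called at the highest concentration were 478 for DMSO, 567 for H2O2 and 0 for MeOH in Caco-2. The any-dose counts there were 569 for H2O2 and 11 for MeOH, and 351 for DCA in RTgill-W1. The wells of a concentration all lay in the same row, so the slope over rows came from the control wells alone. In Caco-2 it was extended to rows A and B, which held no control. Whether those rows follow the slope was not tested. DESeq2 gave 72 genes for any dose and 58 at the highest concentration for MeOH in Caco-2, 198 and 70 for MeOH in Hep G2, and 1256 for DCA and 2087 for DMSO at any dose in RTgill-W1. Without a filter on low counts these became 215 and 82, 394 and 134, and 2311 and 3604.

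The replicate block as a factor gave 83 genes for any dose and 73 at the highest concentration for MeOH in Caco-2, and 181 and 102 for MeOH in Hep G2. The any-dose counts of the human lines were 4237, 1215 and 83 in Caco-2 and 3401, 1188 and 181 in Hep G2 with it, for DMSO, H2O2 and MeOH. The check of the pairs was mixed. Control wells entered it as the mean of each block. Residuals of different groups in the same block correlated above 0.1 in 62 of 108, 69 of 100 and 98 of 108 pairs in Caco-2. In Hep G2 they did in 25, 33 and 63 of 108 pairs. The mean correlation with the other groups was highest for the own block in 88.9%, 88.5%, 96.3%, 81.5%, 81.5% and 100% of cases. This is a hint from the data and not from the design. With the block the lowest active concentration became 0.6 for DMSO (31 genes), 0.83 for H2O2 (32) and 5 for MeOH (24) in Caco-2, and 0.025 for H2O2 (297) and 0.08 for MeOH (130) in Hep G2. In RTgill-W1 the block gave 1612 genes at any dose for DCA and 2381 for DMSO, and a tPOD of 1.23 for DCA. For DMSO in Caco-2 it left 3 lists past the threshold and ended the calls of ATF4 targets (adjusted p = 0.056), the unfolded-protein list (0.052), cholesterol synthesis (0.052) and immediate early genes (0.05). Lists that gained a call were nuclear oxidative phosphorylation (0.043) and actin targets (0.046) for H2O2 and enterocyte markers (0.011) for MeOH, all in Caco-2.

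With an estimated correlation between genes, 0 lists passed for DMSO and 0 for MeOH in Caco-2, and 0 and 0 in Hep G2. With replicate blocks 1 and 2 only, the highest concentration of H2O2 had 564 genes in Caco-2 and 823 in Hep G2, where any dose had 465. For MeOH the any-dose count was 51 in Caco-2 and 9 in Hep G2, with 0 at the highest concentration in Hep G2, and the line difference under H2O2 was 175 genes. Fewer wells entered these fits. For H2O2 in Caco-2 they left 1 well at the highest concentration, since 1 had been left out for depth, so 564 and 175 rest on a group whose spread comes from other groups.

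Leaving out each replicate number of the treated wells in turn, which also leaves fewer wells, gave at the highest concentration 541 to 774 genes for DMSO, 399 to 1058 for H2O2 (530 without number 3) and 9 to 15 for MeOH in Caco-2. It gave 9 to 22 for MeOH in Hep G2, 938 to 1046 for DCA (947 without number 1) and 1441 to 1817 for DMSO (1467 without number 1) in RTgill-W1. The any-dose counts were 380 to 610 for H2O2 (529 without number 3) and 11 to 23 for MeOH in Caco-2, 663 to 730 for H2O2 (696 without number 3) and 44 to 98 for MeOH (48 without number 3) in Hep G2, and 401 to 523 for DCA and 829 to 959 for DMSO in RTgill-W1. Line differences were 1131 to 1469 genes for DMSO and 157 to 319 for H2O2 (176 without number 3), and DMSO differed from MeOH in 147 to 261 genes in Caco-2 (208 without number 2). For H2O2 in Caco-2, leaving out number 1 or 3 left 1 well at the highest concentration. The counts and tPODs of these alternatives, and the line differences of 157 and 176 genes, therefore rest on a group of 1 well and show nothing about its spread.

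The tPOD also moved when replicate numbers were left out: 0.268 to 0.303 for DMSO (0.271 without number 1), 0.239 to 0.463 for H2O2 (0.261 without number 3) and 0.0156 to 0.0213 for MeOH in Caco-2, 0.207 to 0.393 for DMSO in Hep G2, and 0.108 to 0.628 for DCA (0.126 without number 3) and 0.0443 to 0.118 for DMSO (0.0639 without number 2) in RTgill-W1. A response of 2 SD raised it to 1.09, 0.952 and 0.0465 in Caco-2 and 1.7, 1.31 and 0.0366 in Hep G2 for DMSO, H2O2 and MeOH, and to 5 for DCA and 0.517 for DMSO in RTgill-W1. The 25th lowest gene gave 0.13 for DMSO and 0.257 for H2O2 in Caco-2, 0.0216 for DMSO, 0.00807 for H2O2 and 0.0312 for MeOH in Hep G2, and 0.422 for DCA and 0.0277 for DMSO in RTgill-W1. Without a fold filter H2O2 in Caco-2 gave 0.467. Without the highest concentration the tPOD was 0.412 for DMSO and 0.375 for H2O2 in Caco-2, 0.0791 for DMSO and 0.00735 for H2O2 in Hep G2, and 0.21 for DCA and 0.0795 for DMSO in RTgill-W1. For MeOH in Caco-2, leaving out number 1 and taking the 25th lowest gene gave no tPOD, since too few genes had a dose.

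The doses of the treatment field gave a tPOD of 0.255 for DMSO and 0.00553 for H2O2 in Hep G2, 0.0408 for DCA and 0.0068 for DMSO in RTgill-W1. The wells that this field puts at the top in RTgill-W1 had 13 genes called for DCA and 3 for DMSO, and under its order 33 of 626 and 64 of 1322 genes received a dose.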

Other observations

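Replication-dependent histone genes, which are transcribed mainly while DNA is copied, were looked at as a group after their place among the falling genes had been seen. The libraries came from a 3' RNA-seq kit, and how fully it captures the transcripts of these genes was not tested. At the highest DMSO concentration in Caco-2, 0 were up and 45 down of 49 measured, with a median log2 fold change of −3.03 (−3 with RLE factors, and −2.77 with the 6 genes at 0 counts set to their bounds). Camera gave an adjusted p of 2.2e-65, and 2.5e-05 with an estimated correlation. The 2 next concentrations had 2 up and 19 down (median −0.432) and 0 up and 42 down (median −1.75). H2O2 in Caco-2 had 1 up and 28 down of 50 at 3.33 and 0 up and 41 down at 1.67, with medians of −1.24 and −1.27. In Hep G2 the numbers were 0 up and 33 down of 44 for DMSO at 10 (median −2.49), 1 up and 38 down for DMSO at 5 (median −1.81) and 0 up and 36 down for H2O2 at 3.33 (median −2.07). The 7 S-phase genes measured in these Hep G2 wells had medians of −0.914 (4 called down and 1 up), −1.78 (7 down) and −0.237 (2 down). The adjusted p of the histone genes with an estimated correlation was 0.023 for DMSO at 10 and 5.1e-05 for H2O2. With lower MeOH concentrations the group median was above 0 in Caco-2, with 7 up and 0 down of 51 at 5 (median 0.547, adjusted p = 0.0018 with an estimated correlation), 5 up at 2.5 (median 0.303, p = 0.028) and 2 up at 10 (median 0.183, p = 0.18). For MeOH in Hep G2 the medians were 0.0576, 0.367 and 0.333 at 10, 5 and 2.5, and the p was 0.7, 0.09 and 0.35.

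Fewer cells in S phase would lower these histone genes together with other genes of DNA replication. This test was chosen after the fall was seen, and the condition that even the lowest of the other genes stay above the histone median was added before its value was known. The 7 S-phase genes measured at the highest DMSO concentration in Caco-2 had a median log2 fold change of −0.273 (−0.97 to 0.239), and 2 of them were called down. The fall of the histone genes at this concentration was therefore not matched by the S-phase genes. The test takes both sets to follow the share of cells in S phase alike. That was not tested, so fewer cells in S phase is not excluded as the cause. At 5 the same 7 genes had a median of −1.13 (6 called down and 1 up) against a histone median of −0.432, where the histone genes did not pass with an estimated correlation (adjusted p = 0.48). At 2.5 they had a median of −2.01, below the histone median of −1.75, and all 7 were called down.

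The share of counts from mitochondrially encoded genes was 1.45 ± 0.285% in the Caco-2 controls, 2.08 ± 0.454% at the highest DMSO concentration, 3.01 ± 1.01% with H2O2 and 1.53 ± 0.124% with MeOH. In Hep G2 it was 1.15 ± 0.255% in the controls, 4.24 ± 0.612% with DMSO and 1.74 ± 0.225% with MeOH. All MeOH concentrations in Hep G2 had mean shares between 1.46% and 1.74%, those of DMSO below the top between 1.67% and 1.88% and those of H2O2 below the top between 1.52% and 1.72%, all above the controls.

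The total counts of wells at the same plate position correlated between the plates of different lines. Between Caco-2 and Hep G2 r was 0.919 and rho 0.889 over 84 wells (0.9 without the 2 farthest wells), between Caco-2 and RTgill-W1 0.485 and 0.595 over 66 wells (0.432), and between Hep G2 and RTgill-W1 0.582 and 0.759 over 66 wells (0.538). The permutation p was 1e-05 for the first pair, the smallest that 100000 permutations can give, and 4e-04 for the second, and adjusted over the 3 pairs p was 2e-05, 4e-04 and 2e-05. Within groups of the first pair r was 0.737 in 12 control wells, and 0.939, 0.926 and 0.965 in 24 wells each of DMSO, H2O2 and MeOH.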
